A study of Equus caballus with 8 samples.

How the data were processed

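Total RNA from 8 endometrial biopsies was labelled with Cy3, per the labels' protocols, and each sample was hybridised to 1 one-colour Agilent horse array with 45220 spots. The labels put 4 samples in the pregnant day 16 group and 4 in the control day 12 group and give the mare of each sample, and the series' design text pairs the samples of a mare. Per the file headers, the arrays lay on 2 slides of 4 arrays. Slide 1 held mares 1 and 2, slide 2 held mares 4 and 6, and both groups were on each slide. Pregnant arrays were at positions 1 and 3 of a slide and control arrays at positions 2 and 4.

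The authors deposited the output of Agilent Feature Extraction 10.7.3.1 (per the submitters' processing notes and the file headers). The intensity of each spot is given there as a processed signal, which the software has corrected for background and spatial trend, and as median signals of the spot and of its local background. These intensities are not normalized between arrays. The deposited flags mark spots that are well above background, saturated or outliers. The authors also deposited a value table on a log2-like scale with values for 36080 of its 45220 rows, none of them control spots. How it was normalized and filtered is not given in the sources used here. On each array its values follow the rank order of the processed signal, its direction is that of the signal, and its columns are not centred by gene. Its array medians were 8.03 and 7.96 for the pregnant and control array of mare 1, 8.56 and 8.45 for mare 2, 8.45 and 8.40 for mare 4, and 8.15 and 8.11 for mare 6, so levels in that table are alike within mares and not comparable between mares. It was used as an alternative, and chiefly with mare in the model.

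The analysis started from log2 of the processed signal minus each array's 75th percentile over the 43803 non-control spots. Outlier spots, between 25 and 133 per array, were left out, and spots of one probe were averaged, which left 43603 probes. A probe was tested if it was well above background on at least 4 of the 8 arrays (replicate spots: at least 0.5 of them). This kept 36021 probes, of which 1 had too many outlier spots to be estimated. Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with mare as a fixed block and all 8 arrays in the fit. P-values are two-sided, adjusted by Benjamini-Hochberg over all probes tested, and called when under 0.05. For counts of transcripts, each accession was represented by its tested probe with the highest mean level over the 8 arrays. The 1724 probes without an accession were counted as probes only. By limma's estimate 57.1% of the probes tested were unchanged. The 2 arrays of a mare come from the same animal, per the labels. The deviations of a mare's 2 arrays from their group means correlated at 0.59, 0.32, 0.46 and 0.38 for mares 1, 2, 4 and 6. Those arrays also lay at adjacent positions of one slide, so the correlations cannot tell the animal from the position.

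The tests, the filter, the mare block, most alternatives, gene lists and a rule for the genes to name were set before the data were examined. The rule was to name, by gene symbol, the genes with the largest called changes in the same direction in all 4 mares, the members of each list with the smallest adjusted p, and a preset set of genes. The counts by detection, by mare, by slide, by level and by source of the accession, and the comparison between mares, were chosen after the data were seen. The files pair no accession with a gene symbol and no table of names was used here, so the gene lists were not tested and the rule could not be applied. In its place, chosen after the data were seen, the text names the 2 accessions that rose most and the 2 that fell most by the same ranking. No genome positions are given for the same reason.

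The fit was tested on simulated arrays with the residual spread of 35811 real probes and noise drawn independently for each probe and array. With 10000 probes changed, it recovered 72.3% of those changed 1.5-fold, 90.9% of those changed 2-fold and 98.7% of those changed 4-fold, with 385 false calls among 9423. With 200 probes changed, it recovered 2% at 1.5-fold, 46% at 2-fold and 90% at 4-fold, with 7 false calls among 125. Error shared by the probes of an array was not simulated, so these counts do not give the rate of false calls in the real data. The 10000 changed probes held 2500 at each of 1.5-fold, 2-fold, 4-fold and 8-fold. In the real data, 126 probes were called at least 4-fold higher and 120 at least 4-fold lower. Recovery depends on how many probes change and by how much, so the shares recovered do not give the power in the real data. Single values over the 4 mares were tested with exact sign-flip permutations.

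Alternatives were the fit without mare, mare as a random block, slide as a block, quantile normalization, scaling to the median of detected probes, the deposited value table, no filter, a filter on all 8 arrays, an intensity trend with robust eBayes, array quality weights, a mean over the probes of a transcript, stricter thresholds, and leaving out each mare. The planned background correction by normexp on mean signals could not be run because the files used here hold no mean signal, and normexp with an offset of 50 was run on the median signals instead. That setting, scaling to spike-ins, fits with each probe's own variance in place of the moderated one, the fits of a single slide or of 2 mares, and the value table without mare were added after the data were seen. The number of arrays limits the precision of every value.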

Results

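The arrays measured RNA from biopsies of the endometrium, the lining of the uterus, of 4 warmblood mares, numbered 1, 2, 4 and 6 in the labels. Each mare gave 1 biopsy at day 16 of pregnancy, taken after the embryo had been recovered, and 1 biopsy at day 12 of a non-pregnant cycle. The samples used here were therefore 4 pregnant and 4 control, paired by mare. The series' text speaks of more mares than the 4 in the labels. On each one-colour Agilent array, between 35256 and 36802 of the 43603 horse probes were well above background, which is 80.9% to 84.4%. No spot was saturated, and 33593 probes were well above background on all 8 arrays. The 75th percentile of the processed signal ran from 966 to 1695 units on the pregnant arrays and from 1008 to 1432 units on the control arrays. The deposited files name each probe by a transcript or sequence accession and give no gene symbol, so the transcripts below are named by accession and their genes stay unnamed here.

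The principal components of 35811 probes separated the groups before any test. The first component held 37.8% of the variance, and every pregnant array lay on its positive side and every control array on its negative side. The second component held 20.6% of the variance. Both arrays of mare 1 lay at one end of it, and the ranges of mares 2 and 4 overlapped. Pairs of pregnant arrays correlated across probes at 0.982 to 0.986, pairs of control arrays at 0.984 to 0.990, and the 2 arrays of one mare at 0.978 to 0.987. These correlations are across probes within pairs of arrays, and probes are not independent replicates.

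**Figure D1:**
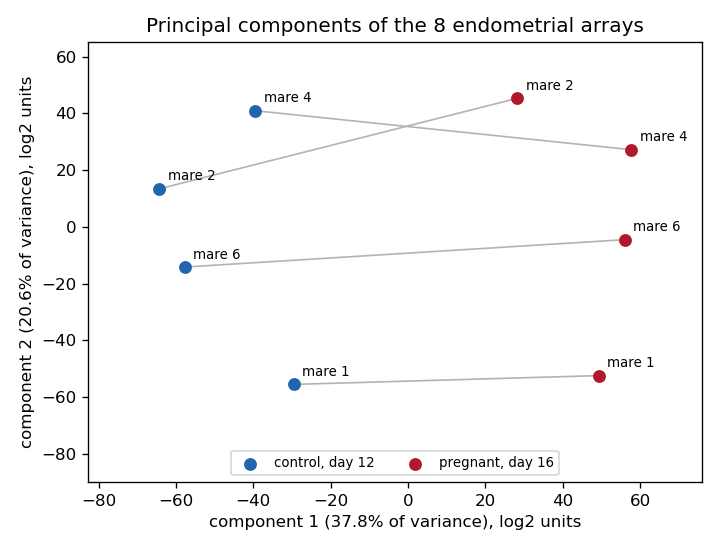
Principal component scores (log2 units) of the 8 arrays, with pregnant day 16 in red, control day 12 in blue and a grey line joining the 2 arrays of a mare. Component 1, on the horizontal axis, holds 37.8% of the variance and parts the 4 pregnant arrays from the 4 control arrays, and component 2, on the vertical axis, holds 20.6%.

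The main question was which transcripts differ between pregnant day 16 endometrium and the cyclic day 12 endometrium of the same mare. The endometrium of pregnant mares differed from that of controls at 2367 of 19767 transcripts tested, with 1203 higher and 1164 lower in pregnant mares (limma with mare as a block, Benjamini-Hochberg adjusted p under 0.05). At the level of probes, 2451 were higher and 2321 lower of 36020 tested, which is 13.2% of them. The median log2 change was 0.82 among the probes called higher and -0.73 among those called lower. Among the called transcripts, 372 were at least 2-fold higher and 315 at least 2-fold lower. At 4-fold or more, 60 transcripts were higher and 64 lower, and at 8-fold or more 19 were higher and 17 lower. The median standard error of a log2 change was 0.13 over all probes tested. The number of arrays limits this precision, and the calls rest on limma's pooling of the variance over probes. With each probe's own variance alone, 1 probe was called higher and 4 lower at the same threshold, while 4372 were higher and 4581 lower at an unadjusted p under 0.05.

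The near-equal split into higher and lower transcripts holds for scaling to each array's 75th percentile, where 51.4% of the called probes were higher. Scaling instead to the 8 spike-in transcripts detected on every array, which are added to each RNA in fixed amounts, moved the median change of all probes from 0.02 to 0.30 (log2). On that scale 4055 probes were called higher and 624 lower (86.7% higher), but its p-values were too small: the offset that all probes of an array share made limma's estimate of the prior degrees of freedom infinite. With each probe's own variance, the spike-in scale gave 0 calls in limma's unmoderated fit, and 4338 probes higher and 504 lower at an unadjusted p under 0.05. The spike-ins were lower on the pregnant array in 3 of 4 mares, by a mean log2 difference of -0.28 ± 0.40 (SD, n = 4; two-sided exact sign-flip permutation test, p = 0.25), and 4 mares cannot give a p under 0.125. All directions are given relative to the 75th percentile of each array.

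The transcript that rose most was DN508408, a GenBank sequence entry, whose signal was 258-fold higher in pregnant endometrium. Its log2 change was 8.01 ± 0.55 (limma's SE, n = 4 mares), with an adjusted p of 0.0027 in limma. This SE, here and below, pools the variance over probes and is not the SE of the 4 mare changes. Only transcripts that changed the same way in all 4 mares were named, and this one was higher by 5.93 in mare 1, 7.85 in mare 2, 8.66 in mare 4 and 9.60 in mare 6. All 5 of its probes were called higher, with log2 changes between 8.01 and 8.23. With normexp on the median signals the log2 change of DN508408 was 7.21, and without 1 mare it was 7.48 to 8.70. Its level was even among the pregnant arrays, at 4.28 ± 0.37 (log2 relative to the 75th percentile, SD, n = 4), and more variable among the controls, at -3.73 ± 1.57 (SD, n = 4), where it was nevertheless well above background on every array.

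The second by estimated change was the Ensembl transcript ENSECAT00000022717, measured by 1 probe. Its mean rise in the processed signal was at least 47.0-fold, a bound that allows for undetected signal but not for sampling error or other processing. The transcript was well above background on all 4 pregnant arrays and on 2 of the 4 control arrays, and its signal on the other 2 was below the lowest signal well above background there, which stands in for it in this bound. With the measured signals its log2 change was 5.94 ± 0.70 (limma's SE, n = 4 mares; limma adjusted p = 0.0071), with a 95% confidence interval of 4.23 to 7.64. That estimate was 3.12 with normexp on the median signals and 4.23 in the deposited value table. Its level was -1.45 ± 0.99 on the pregnant arrays and -7.39 ± 1.13 on the control arrays (log2, SD, n = 4 each), and the change was smallest in mare 4, at 3.13.

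The 2 transcripts that fell most were the RefSeq transcript XM_001493219 and the Ensembl transcript ENSECAT00000019537. XM_001493219 had a log2 change of -4.46 ± 0.39 (limma's SE, n = 4 mares; limma adjusted p = 0.0036), which is a signal 22.0 times as high in the controls, and both of its probes were called lower. Its level was 1.74 ± 0.45 on the control arrays and -2.72 ± 1.30 on the pregnant arrays (log2, SD, n = 4 each). ENSECAT00000019537, with 1 probe, had a log2 change of -4.42 ± 0.49 (limma's SE, n = 4 mares; limma adjusted p = 0.0063), and its level went from -0.73 ± 0.91 in controls to -5.16 ± 1.68 in pregnant mares (log2, SD, n = 4 each). With normexp on the median signals the log2 change of ENSECAT00000019537 was -2.96. Both transcripts were lower in all 4 mares, as the rule for naming them required, and well above background on all 8 arrays.

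**Figure D2:**
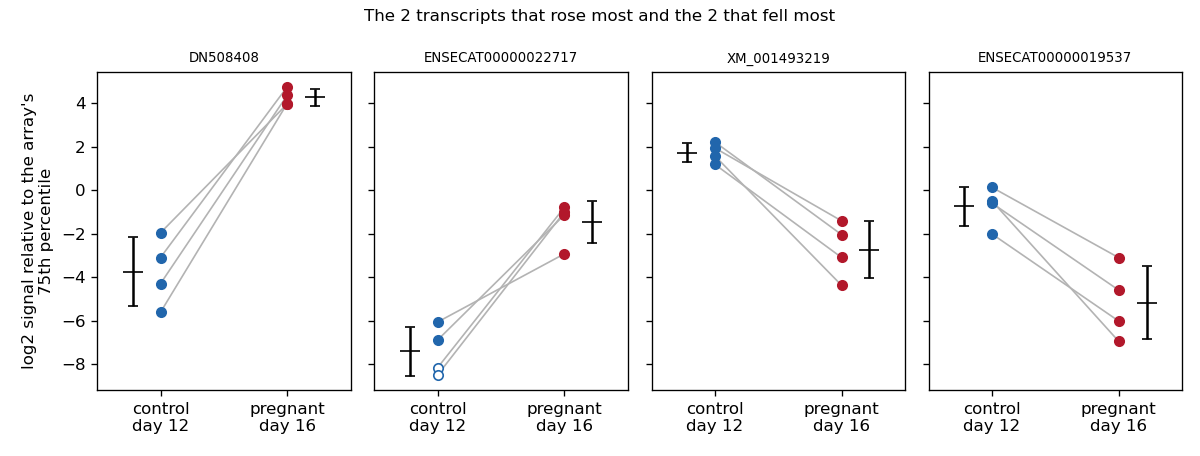
Signal of the 2 transcripts that rose most and the 2 that fell most, as log2 of the signal relative to each array's 75th percentile (vertical axis), on the control day 12 arrays in blue and the pregnant day 16 arrays in red. Points are single arrays, open points are not well above background, grey lines join the arrays of a mare, and black marks are the mean ± SD of 4 arrays. Every line of DN508408 and ENSECAT00000022717 goes up, and every line of XM_001493219 and ENSECAT00000019537 goes down, as the rule for naming them required.

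Some probes crossed the threshold of detection between the groups, which need not mean that a transcript was absent from either group. There were 15 probes, 2 of them without an accession and the others from 11 accessions, that were well above background on all 4 pregnant arrays and on none of the control arrays. Of these, 14 were called higher, and over all 15 the signal was at least 1.52-fold to at least 5.25-fold higher. A further 32 probes, 4 of them without an accession and the others from 22 accessions, were well above background on all 4 control arrays and on none of the pregnant arrays. Of these, 28 were called lower, and over all 32 the control signal was at least 1.11-fold to at least 4.76-fold higher. Detection on the same arrays chose both sets of probes, so their calls are no separate support. Without 1 mare, when fewer arrays had to meet the rule, the numbers were 27 to 82 for pregnant and 44 to 76 for control, with the 82 found without mare 4. These folds are lower bounds for undetected signal in this processing and do not allow for sampling error. The dim group was set to the lowest signal well above background on each of its arrays, or to the probe's own signal where that was higher.

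Of 6572 transcripts with at least 2 probes tested, 1246 had a called probe and 887 of these had at least 2. In 704 transcripts every probe was called in one direction, and in 0 of the 887 were probes called in opposite directions by limma. At an unadjusted p under 0.05, 6 of 2027 transcripts with at least 2 such probes had probes in both directions. Probes of a transcript were read on the same arrays and samples, so their agreement is no independent support for the calls. Transcripts of every source were among those that changed. The called share was 11.9% of 15960 Ensembl transcripts (949 higher, 949 lower), 12.8% of 1355 RefSeq transcripts (95 higher, 78 lower) and 12.1% of 2452 other sequence entries (159 higher, 137 lower). Differences between these shares were not tested.

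Counted per mare, the change ran the same way in all 4 mares for 39.8% of 35811 probes. For unchanged probes 12.5% is expected by chance, if errors are independent between mares and as often up as down. An error tied to array position, which went with group, would break that condition. Of the probes that ran the same way, 7423 were higher and 6847 lower. The change in one mare correlated with that in another at 0.50 to 0.63 across probes, over the 6 pairs of mares. For probes called in the other 3 mares only, the left-out mare changed in the same direction at 95% of 2239 probes for mare 1, 87.4% of 2873 for mare 2, 96.1% of 1730 for mare 4 and 96.5% of 1944 for mare 6. Fitted on its own, slide 1 (mares 1 and 2) gave 120 probes higher and 65 lower, and slide 2 (mares 4 and 6) gave 1216 higher and 914 lower.

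Without mare as a block the count fell to 1352 probes higher and 1376 lower, with slide as the block in place of mare it was 1271 and 1288, and without mare 1, 2, 4 or 6 the total fell from 4772 to 2239, 2873, 1730 or 1944. Every pregnant sample was taken at day 16 after embryo recovery and every control at day 12, so pregnancy, day and the recovery procedure cannot be told apart in these data. Pregnant arrays held positions 1 and 3 of each slide and control arrays positions 2 and 4, so position went with group too.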

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

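Of 24 sets of 4 values checked for an array far from the others, 1 was set apart, and chance alone sets apart about 1 in 20. ENSECAT00000022717 had a level of -2.92 on the pregnant array of mare 4, against -1.13 to -0.78 on the other pregnant arrays (log2 relative to the 75th percentile). The gap was 0.838 of the range of the 4 arrays.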

How the results depend on the processing

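Normexp on the median signals, spike-in scaling, fits with each probe's own variance, fits of 2 mares and the value table with no block were chosen after the data were seen. The number of calls depended on the setting. Of the 4772 called probes, 4 changed sign under normexp on the median signals. Most other settings keep the estimates, move them all by one offset or reuse arrays that selected the calls, so they hardly test the direction. The counts of probes higher and lower stayed within 1.5 times of 2451 and 2321 under 8 alternatives, among them quantile normalization (1996 and 2542) and the deposited value table (2603 and 2726). With no replicate block they were 1352 and 1376 probes (659 and 723 transcripts), and 2639 of the 4772 probes were kept. With slide as a block in place of mare they were 1271 and 1288 (619 and 670 transcripts). The deposited value table with no replicate block gave 400 and 367 (197 and 199 transcripts). No filter gave 1480 and 1344 (699 and 697 transcripts), with more probes to adjust over. A 2-fold minimum gave 801 and 619 (372 and 315 transcripts), and an adjusted p under 0.01 gave 499 and 483 (234 and 250 transcripts). Each probe's own variance, without limma's pooling, gave 1 and 4 probes (0 and 3 transcripts). Spike-in scaling gave 4055 and 624 (2078 and 308 transcripts), with p-values too small because the prior degrees of freedom were infinite, and 0 and 0 (0 and 0 transcripts) with each probe's own variance. Leaving out 1 mare gave 947 to 1622 probes higher and 783 to 1251 lower (450 to 810 and 404 to 639 transcripts). Fits of 2 mares gave 120 and 65 on slide 1 (47 and 39 transcripts), 1216 and 914 on slide 2 (593 and 462 transcripts), and 52 and 20 for the 2 mares with the highest array weights, 1 and 4 (25 and 9 transcripts). With normexp and in the deposited value table the log2 change was 3.12 and 4.23 for ENSECAT00000022717 and -2.96 and -3.78 for ENSECAT00000019537. Their adjusted p ranged up to 0.35, its value with spike-in scaling and each probe's own variance, from 3.04e-175 for DN508408 under moderated spike-in scaling. None of the 4 was called with each probe's own variance (adjusted p 0.082 for DN508408, 0.11 for ENSECAT00000022717, 0.090 for XM_001493219, 0.11 for ENSECAT00000019537), and in mares 1 and 4 alone ENSECAT00000019537 was the only one called (adjusted p 0.062, 0.083 and 0.051 for the others in that order). Without 1 mare, the probes detected on all pregnant arrays alone numbered 27 to 82 and those detected on all control arrays alone 44 to 76. The share of called probes higher in pregnant mares crossed 50% in the lowest tercile of level under quantile normalization (48.4%), and in the highest under spike-in scaling (76.3%), on slide 1 (52.2%) and in the 2 mares with the highest weights (100% of 2 probes). In the same order, the opposite tercile was at 41.3%, 89.9%, 70% and 57.5%. Apart from settings whose construction shows it (fewer arrays, more probes tested, no pooled variance), the cause of a moved count was not tested. Signal over background limits the values of dim probes. Tests of the gene lists, and normexp on mean signals, were not run.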

Other observations

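Chosen after the data were seen were the comparison between mares, the split of the calls by level, the spike-in tests and their criteria, the test of the spread between mares, and the settings named as such in the account of the processing. The overall counts after quantile normalization were known when its test by level was written.

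Few probes were called different between mares, and a probe that was not called may still differ. With group in the model, 330 of 35811 probes (0.92%) differed between the 4 mares (limma F-test, adjusted p under 0.05), and 93 of these were also called between the groups. By detection, 393 probes, more than were called, had both arrays of some mares well above background and neither array of the others. For 16 of the 393 the bound on the difference was at least 4-fold. Of these 16, 10 were detected in 1 mare alone (6 in mare 4, 3 in mare 1 and 1 in mare 6), 5 were missing from 1 mare alone, and 1 was detected in 2 mares. The largest such bound was at least 58.5-fold. The number called depends on the processing: it was 299 after quantile normalization, 1568 with normexp, 84 with no filter, 528 with the filter on all 8 arrays and 15022 in the deposited value table, whose levels are not comparable between mares.

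Slide alone does not account for the differences between mares. Pairs of mares on one slide differed at a mean of 200 probes and pairs on different slides at 140, so the first was 143% of the second. The pairs on one slide differed at 213 and 187 probes and the others at 75 to 261, so a contribution of slide cannot be excluded. A sequence variant under a single probe would leave the other probes of the transcript unaffected, yet 194 of 213 called probes that had a partner (91.1%) had another probe with an unadjusted p under 0.05 between mares, against 26.6% of all probes. Probe sequences were not used here, so overlapping probes that share a variant remain open. Inherited differences in expression, uneven sampling of the tissue and the adjacent positions of a mare's arrays also remain open and were not tested.

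In the limma fit without mare, the 8 arrays were split into 4 and 4 in 35 ways. Only the real split, 1 of the 35, called as many probes (2728, highest other 12) or transcripts (1382, highest other 10). That would exclude chance only if the arrays of a mare were independent. The deviations of a mare's 2 arrays from their group means correlated at 0.32 to 0.59, so these splits do not exclude chance. In the fit with mare the real one of the 8 ways to swap arrays within mares called 4772 probes and 2367 transcripts and the highest other 0 of each (1393 probes at an unadjusted p under 0.05, against 11284), and 8 splits are too few for a share under 0.05. An effect of labelling, hybridisation or array position and one of the groups cannot be told apart, because 0 control arrays lay at the positions of pregnant arrays. Pregnancy, the later day and the recovery of the embryo cannot be told apart, because there were 0 arrays of non-pregnant mares at day 16.

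Called probes leaned upward among dim probes and downward among bright ones: 1052 were higher in pregnant mares and 454 lower in the lowest tercile of mean level (69.9% higher), and 491 were higher and 1070 lower in the highest (31.5% higher). Under quantile normalization the shares were 48.4% in the lowest tercile and 41.3% in the highest. The lean remained with normexp on the median signals (59.3% and 35.7%) and with scaling to the median of detected probes (62.9% and 23.8%). It also remained in the deposited value table (60.9% and 36.2%). Spike-in scaling, which moves all probes of an array by one offset, gave 89.9% and 76.3%, so the lowest tercile kept the larger share. A level-dependent error of labelling, hybridisation or scanning would bend the spike-ins too. Over the 8 spike-ins, whose levels span -6.44 to 6.94, the difference changed by 0.0036 per log2 unit of level against -0.021 over all tested probes. The spike-ins' slope was the higher in 4 of 4 mares, by a mean of 0.025 ± 0.0044 (SD, n = 4; two-sided exact sign-flip permutation test, p = 0.125, the smallest possible), which argues against such an error as the whole cause. Quantile normalization, which gives every array the same distribution, reduced the gap between these terciles to 7.16 percentage points, as it would if one factor per array were too simple a scaling. It would do the same if the distribution of transcript levels truly differed between the groups, so such a difference may contribute and was not tested apart.

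The spread between mares was larger among pregnant than among control arrays. The median SD of a probe was 0.26 over the 4 pregnant arrays and 0.21 over the 4 control arrays, and 63.3% of 35811 probes had the larger SD in pregnant mares. The ratio of the medians, 1.24, was the farthest from 1 of the 8 ways to swap arrays within mares (two-sided exact permutation test, p = 0.125, the smallest that 8 splits can give), so it did not pass 0.05.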
